A study of Mus musculus with 10 samples.

How the data were processed

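Total RNA from the femurs of 10 male ICR mice aged 6 months was labelled with Cy3 and hybridised to Agilent one-colour expression arrays, with 1 array per animal. Per the labels' protocols, 5 mice moved freely and 5 were suspended by the tail so that the hindlimb muscles carried no load, and the bones were taken after 24 h. The labels number the animals of each group separately, so the arrays are biological replicates. The only comparison the design holds is unloaded minus control.

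The deposited scanner files give spot intensity on a linear scale. Per the file headers, the authors' spots were read with Agilent Feature Extraction 9.1.3.1 under protocol GE1-v5_91_0806 on Agilent design 014868, with a background correction that the headers give only as a code, spatial and multiplicative detrending within each array, and no scaling between arrays. The deposited series matrix gave intensity on the same linear scale, with column medians of 335, 332, 303, 261 and 306 for controls 1 to 5 and 315, 269, 253, 311 and 291 for unloaded animals 1 to 5. Set against each array's processed signal, its ratios lay between 0.995 and 1.005 on all 10 arrays, as rounding to 3 significant digits gives, so its scale is known, it was uncentred and, with a single colour, it has no direction. It was used as an alternative.

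Each array carried 45018 spots, of which 43379 held gene probes, 41174 different probes in all, and 245 of these were spotted 10 times. Spots of a probe were averaged on the log2 scale. A total of 97 gene spots over all arrays that the scanner software marked as outliers were left out. No gene probe was saturated in most of its spots on any array, and no gene spot had a signal of 0 or less. The values tested were log2 of the processed signal minus the array's 75th percentile of it. Before scaling, that percentile lay between 637 and 903 intensity units. Between 89.8% and 95.5% of the spots of an array were well above background. The number of arrays limits the precision of every value given here.

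A probe was tested when it was well above background on at least 4 of the 5 arrays of a group and measured on at least 3 arrays of each group, which 38629 probes were. The minimum of 3 measured arrays was set after the data were seen, because removing every probe with a marked spot would have lost bright genes such as Bglap; 79 tested probes lacked a value on some array. Probes were named through a RefSeq gene list of assembly GRCm38.p6, which served for names alone. Of the gene probes, 22951 were named by their accession, 3109 by an older name that matched a single gene, 6659 already had a current name and 8455 kept the name in the file. The tested probe with the highest mean over all arrays stood for a gene, which gave 18955 genes with a symbol. Of the genes that the rule for named genes takes, 74 had more than 1 tested probe.

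Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with no covariate, and a probe was called at a Benjamini-Hochberg adjusted p below 0.05. Before the data were examined, 31 gene lists were fixed, 13 of cell type markers and 18 of pathways or gene families. They were tested with limma's camera at a preset correlation of 0.01 between genes, over 18908 genes measured on all arrays, and adjusted over the 31 lists. Beside it stood camera with a correlation estimated from the data, fry, which asks of a list on its own whether its genes move one way, and an exact two-sided permutation test of the list's mean per array over the 252 assignments of 5 arrays, whose smallest possible p is 0.00794. After adjustment over the 31 lists that p falls below 0.05 only where several lists reach it together, so the adjusted permutation test has little power. Files were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9.

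The genes named in the text follow a rule fixed at the same time. The rule took up to 12 genes with the largest rise and up to 12 with the largest fall among called genes, or, where none passed in a direction, the 6 with the smallest p. It also took up to 4 members of each described list, called members first and then by p. A further 13 genes were given whatever their result: Sost, Dmp1, Tnfsf11, Tnfrsf11b, Ctsk, Acp5, Col1a1, Bglap, Runx2, Dkk1, Fkbp5, Per1 and Dbp. Names that are only clone or prediction numbers were passed over. Of the list members the rule takes, the report gives the first 1 to 4 of each list and leaves out the others, and 1 gene that the rule takes is not reported here.

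The alternatives covered the background correction, the scaling, the filter on dim probes, the series matrix, the variance model, array weights, a minimum fold, the threshold, body weight, slide, the replicate number, the choice of probe, the list test and each array left out in turn. The procedure was tested on simulated arrays with the means and spreads of 38550 probes, of which 200 were changed. For the comparison of 5 unloaded with 5 control arrays it recovered 65.7% of changes of 1.5-fold, 83.6% of changes of 2-fold and 98.5% of changes of 3-fold, with 5 false calls among 170. A simulated shift of 0.3 on the log2 scale in 1 list was called, and 0 of the other lists were. Smaller shifts were not simulated, while the largest difference of a list called in the real comparison was 0.25, for cartilage. The simulated genes varied independently of each other, which the genes of a real list need not do. The adjustment is stricter where fewer probes pass. The recovered shares therefore hold for 200 changed probes and do not carry over to the real comparison, which called 1 probe. There Foxa2, at 1.88-fold, was not called (limma adjusted p = 0.131).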

Results

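Gene expression was measured in the femur of 5 freely moving control mice and of 5 mice whose hindlimbs had been unloaded by tail suspension for 24 h. Hindlimb suspension removes weight bearing and muscle loading from the hind legs, and the comparison asks which transcripts of the femur differ after 1 day of it. The control mice weighed 28.6 g ± 1.78 (SD, n = 5) and the unloaded mice 27.3 g ± 1.72 (SD, n = 5), a difference within the spread of the animals (exact permutation p = 0.278). Signals are given on the log2 scale relative to the 75th percentile of each array, and every difference is unloaded minus control. The arrays lay on 3 slides: slide 1 held 4 control arrays, slide 2 held 1 control and 3 unloaded arrays, and slide 3 held 2 unloaded arrays.

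After 24 h of unloading, Ddit4 rose in the femur. Ddit4, an inhibitor of mTOR signalling that is induced by stress and glucocorticoids, went from 3.56 ± 0.15 (SD, n = 5) in control to 4.73 ± 0.23 (SD, n = 5) in unloaded bone, a 2.26-fold increase (log2 fold change 1.17, SE 0.12, limma adjusted p = 0.00794). All 5 unloaded animals lay above all 5 controls. It was the only one of 38629 probes called, and 0 probes were called lower. The smallest adjusted p among the other probes was 0.131. At an unadjusted p below 0.05 limma gave 6225 probes, where 1931 would pass on average by chance. Probes that vary together widen the spread around that number. Other splits of the 10 arrays gave a median of 1328, but 4 of 100 splits, the real one included, gave as many, up to 9225. Of the 6225 probes 3939 were higher and 2286 lower, but with quantile normalization the split turned to 2095 higher and 2938 lower, so no general direction can be read from it. The groups did not overlap for 1221 probes, 3.16% of those tested, where 0.794% is the share expected by chance. How far that share varies between other splits was not computed, and slide largely follows group, so the excess is not read as an effect of unloading.

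The call of Ddit4 was lost without some single arrays and with slide as a fixed block, although its log2 fold change moved little. With slide as a random block Ddit4 was called (limma adjusted p = 0.00565), but arrays of a slide correlated at -0.03 in that fit, so that block removes little of slide. On slide 2 alone, and equally with slide as a block, its log2 fold change was 1.21, with an adjusted p of 0.267 in the blocked fit, in which slide 2 alone informs the difference and holds a single control. Over 28 alternatives its adjusted p lay between 0.000660 and 0.414. It lay between 0.0503 and 0.0567 without control 4, control 5, unloaded 1, unloaded 3 or unloaded 4, with log2 fold changes between 1.14 and 1.15.

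**Figure D1:**
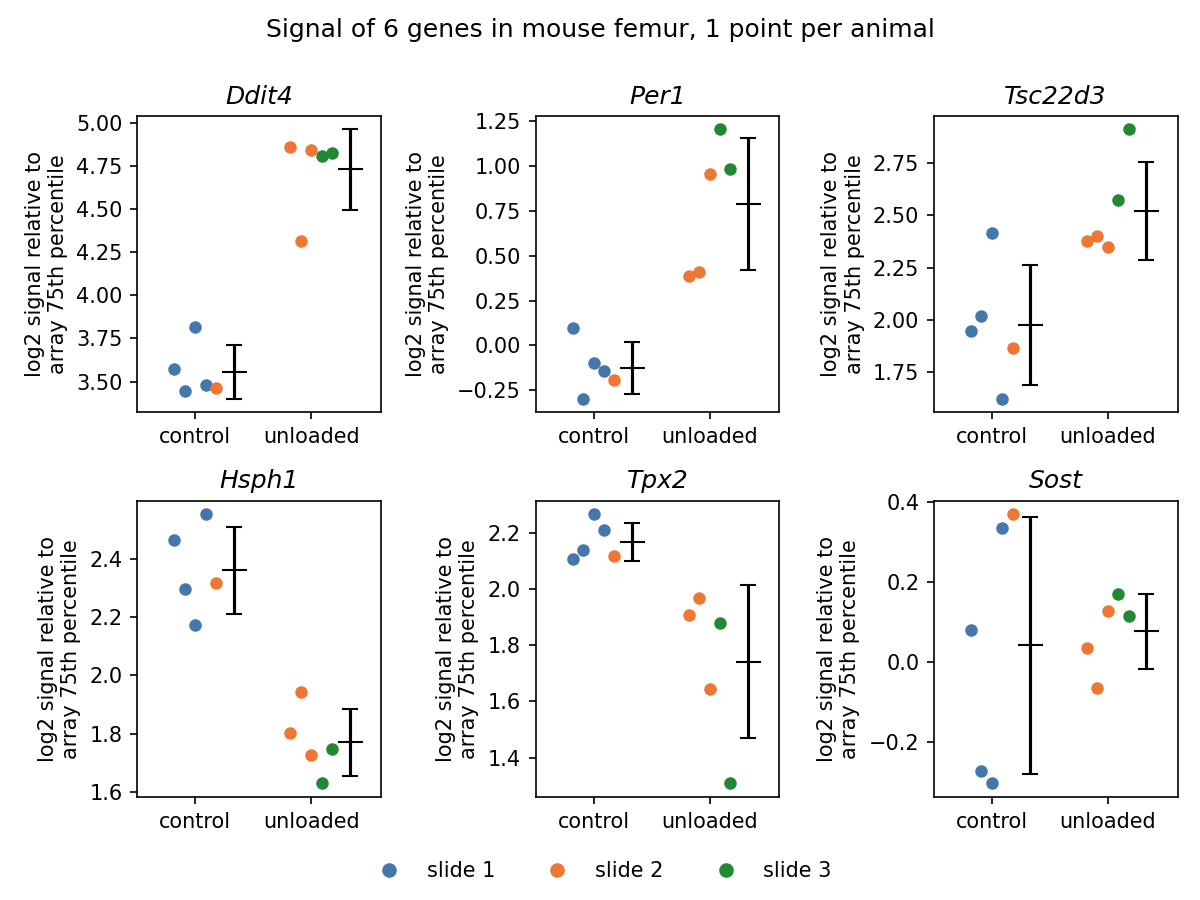
Log2 signal relative to the array's 75th percentile of 6 genes in control and unloaded femurs, with 1 point per animal coloured by slide and the mean ± SD of 5 animals in black. Ddit4 separates the groups, from 3.56 in control to 4.73 in unloaded bone, while Sost overlaps between them; of these genes Ddit4 alone was called.

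Genes that respond to glucocorticoids, the stress hormones of the adrenal cortex, were higher as a group in unloaded femur. Their mean differed by 0.22 on the log2 scale, with SDs between animals of 0.07 in both groups (camera adjusted p = 0.00714). With an estimated correlation the adjusted p was 0.774. The exact permutation test of the list's mean gave p = 0.0159, or 0.164 adjusted over the lists, and fry gave an adjusted p of 0.0262. Of 27 members tested, 21 had a positive and 6 a negative difference. Ddit4 was the 1 member called over all probes, and 7 were called when adjusted over the list alone, 6 of them higher. Per1, a core gene of the circadian clock, was 1.89-fold higher (log2 fold change 0.92, SE 0.16) with all 5 unloaded animals above the controls, but an adjusted p of 0.153 over all probes. Errfi1, a feedback inhibitor of EGF receptor signalling, had a log2 fold change of 0.61 (SE 0.14). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, had 0.55 (SE 0.15). The member lower when adjusted over the list alone was Foxo1, at -0.39 (SE 0.12), named after its values were seen. Fkbp5, a widely used glucocorticoid target, had a log2 fold change of 0.20 (SE 0.12, adjusted p = 0.399). On slide 2, which has 1 control, the list's difference was 0.21, and without the array of unloaded animal 5, which stood apart from the rest, it was 0.19.

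Heat shock genes were lower as a group. The mean of 19 members, chaperones and their partners that assist protein folding, differed by -0.17 on the log2 scale, with SDs of 0.05 in control and 0.08 in unloaded animals (camera adjusted p = 0.000100). With an estimated correlation the adjusted p was 0.207. All 5 unloaded animals lay below all 5 controls, the exact permutation test gave p = 0.00794, or 0.123 adjusted over the lists, and fry gave an adjusted p of 0.0262. Negative differences were found for 15 members and positive ones for 4. None was called over all probes, and 2 were lower when adjusted over the list alone. These were Hsph1, a large heat shock chaperone, 1.51-fold lower (log2 fold change -0.59, SE 0.10), and Chordc1, a co-chaperone, at -0.47 (SE 0.13). Hspd1, the mitochondrial chaperonin, had -0.33 (SE 0.11), and Cacybp -0.25 (SE 0.10). Within slide 2 the list's difference was smaller, at -0.07 (adjusted p = 0.146 with slide as a block, range over alternatives 4.49e-05 to 0.163), and it was -0.14 without unloaded animal 5.

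Camera called 3 further lists, and each lost the call with an estimated correlation. Fry called none of them, with adjusted p of 0.435 for proliferation, 0.0654 for T and NK cells and 0.776 for cartilage. Proliferation genes differed by -0.11 (camera adjusted p = 0.000100; adjusted p = 0.774 with an estimated correlation; exact permutation p = 0.0952). The sign was negative for 31 of 45 members and 0 members were called, with Tpx2, a spindle assembly factor, at -0.43 (SE 0.12), the mitotic kinesins Kif11 and Kif23 at -0.35 and -0.33 (SE 0.10 each) and Mki67 at -0.38 (SE 0.13). For Kif11, 2 of 3 probes shared the sign. Without unloaded animal 5 the list's mean difference was -0.08, and within slide 2 it was -0.21. T and NK cell markers differed by 0.16 (camera adjusted p = 0.0266; adjusted p = 0.774 with an estimated correlation; exact permutation p = 0.0238, or 0.185 adjusted over the lists). Cd8b1 and Cd247, parts of the T cell coreceptor and receptor, had log2 fold changes of 0.51 (SE 0.16) and 0.24 (SE 0.10), and Klrb1c and Cd3g had 0.33 (SE 0.11) and 0.23 (SE 0.10). For Cd8b1 and Klrb1c the other of 2 probes had the opposite sign. Of 21 members 18 had a positive difference and 0 were called. This list did not hold its direction within slide 2, where its mean difference was -0.01. Control 5, the single control there, lay 0.17 above the other controls, so slide or that animal may account for the difference. That rests on 1 control and is not settled. Without control 2 the difference was 0.13 and not called (adjusted p = 0.0873, range over alternatives 0.00291 to 0.957), and without unloaded animal 5 it was 0.14.

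Cartilage genes differed by 0.25 with SDs of 0.29 in each group (camera adjusted p = 0.0266; adjusted p = 0.774 with an estimated correlation; exact permutation p = 0.198). The difference was positive for all 16 members, which varied together from animal to animal with an estimated correlation of 0.76, and 0 were called. Col9a3 and Col9a2, which encode chains of a cartilage collagen, had 0.48 (SE 0.21) and 0.38 (SE 0.20), Col2a1, the main cartilage collagen, 0.37 (SE 0.20) and Comp 0.32 (SE 0.16). The call of the list was lost without control 1 (0.22, adjusted p = 0.0590), control 5 (0.17, adjusted p = 0.282), unloaded 1 (0.22, adjusted p = 0.0863) or unloaded 2 (0.15, adjusted p = 0.282), the range over alternatives being 7.41e-18 to 0.282. The difference was 0.34 without unloaded animal 5 and 0.75 within slide 2. The 5 calls made by camera at its preset correlation cannot be told from chance by their number, since 97 of 100 splits of the 10 arrays, the real one included, gave 5 or more.

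**Figure D2:**
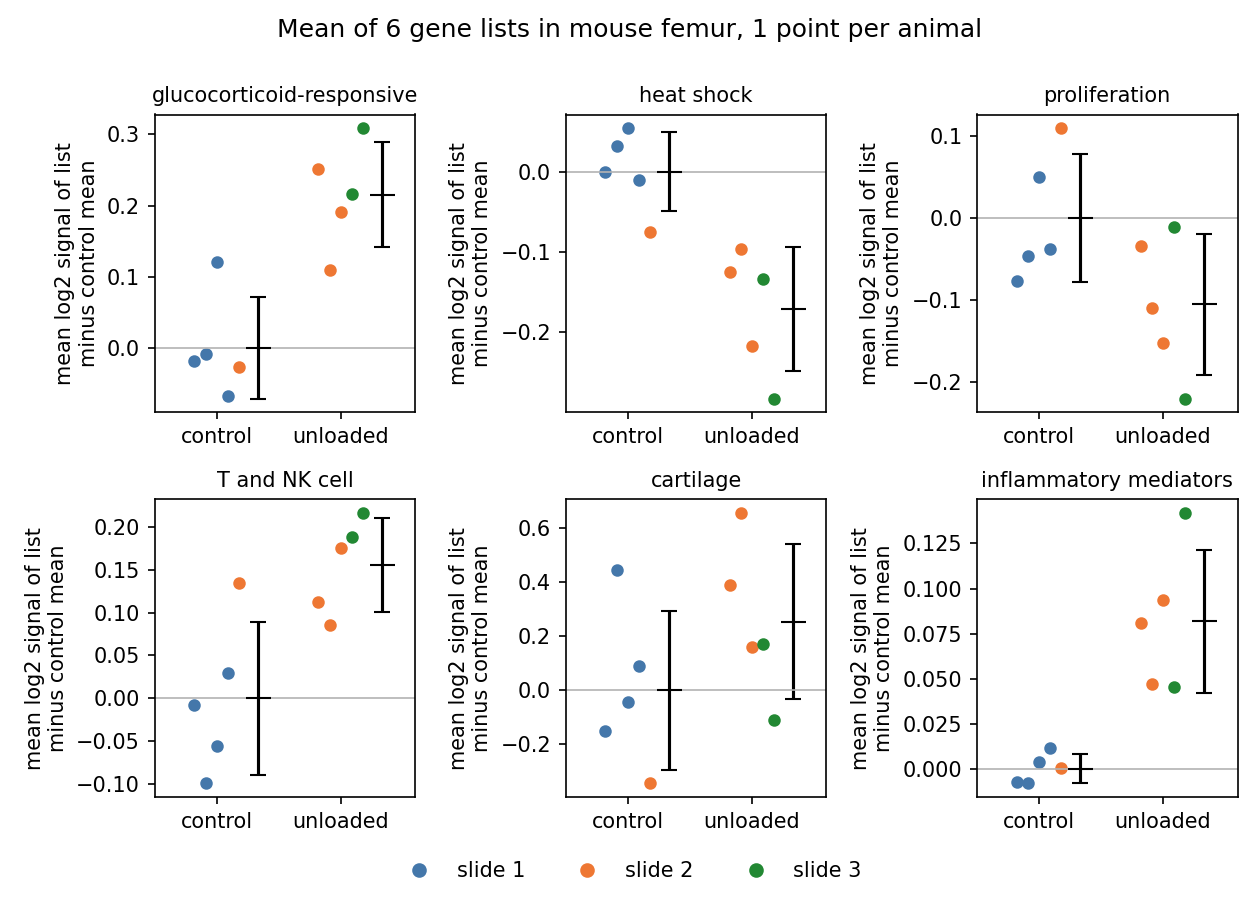
Mean log2 signal of 6 gene lists per animal, relative to the control mean, with points coloured by slide and the mean ± SD of 5 animals in black. The heat shock and inflammatory mediator lists separate the 5 unloaded from the 5 control animals, while cartilage genes overlap widely. The control animal on slide 2 lies nearest to the unloaded animals for heat shock genes and among them for T and NK cell genes.

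No bone cell gene was called over all probes. Sost, which encodes the Wnt inhibitor sclerostin made by osteocytes, had a log2 fold change of 0.03 with a 95% interval from -0.26 to 0.33. Dmp1 and Dkk1, an osteocyte matrix protein and a Wnt inhibitor, had 0.29 (interval -0.05 to 0.63) and 0.11 (-0.21 to 0.42). Tnfsf11, the osteoclast-inducing cytokine RANKL, had 0.18 (-0.11 to 0.47), and its decoy receptor Tnfrsf11b -0.07 (-0.44 to 0.29). The osteoclast enzymes Ctsk and Acp5 had 0.06 (-0.28 to 0.40) and 0.13 (-0.18 to 0.45). In the osteoblast series Col1a1 had 0.08 (-0.09 to 0.25), Bglap, which encodes osteocalcin, 0.04 (-0.28 to 0.35) and Runx2 0.01 (-0.24 to 0.25). The clock output gene Dbp had -0.02 (-0.33 to 0.28). None of the 13 genes fixed for this purpose was called, and their adjusted p lay between 0.153 (Per1) and 0.974 (Runx2). Median scaling moved all list means by the same -0.10, and Sost, Ctsk, Col1a1, Bglap and Runx2, which lie near 0, were negative under it. Bglap also changed sign with quantile normalization, and Dbp with quantile normalization and cyclic loess. Within slide 2, which has 1 control, Sost had -0.34, Tnfrsf11b 0.49 and Bglap -0.00793, each with the sign turned, and the values of Sost and Tnfrsf11b lay outside the intervals given. Bglap was measured on 4 of the 5 unloaded arrays. Probes of Col1a1, Dkk1 and Runx2 disagreed in sign, with 2 of 3, 1 of 2 and 3 of 4 on the side given.

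**Figure D3:**
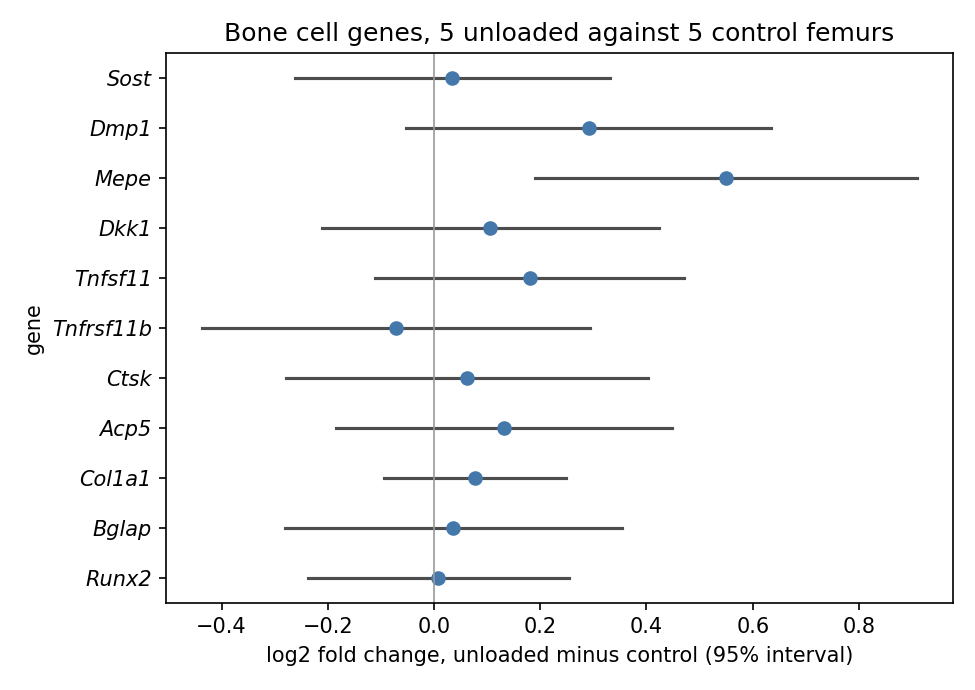
Log2 fold change, unloaded minus control, of 11 bone cell genes with 95% intervals from limma (5 animals per group, but 4 unloaded animals for Bglap). All intervals except that of Mepe include 0, and none of these genes was called after adjustment.

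The bone cell lists and the list of fibrillar matrix and remodelling were not called in the comparison of all arrays. All of these but the osteoclast list were called higher with slide as a block, in which slide 2 alone informs the difference and holds a single control. Among 14 osteocyte genes 13 had a positive difference, the mean being 0.12 (camera adjusted p = 0.291), or 0.28 with slide as a block (adjusted p = 0.000562, range over alternatives 0.000420 to 0.701). The largest belonged to Mepe, a mineralization-regulating matrix protein of osteocytes, at 0.55 (SE 0.17, adjusted p = 0.240), with all 5 unloaded animals above the controls, and Fbln7 had 0.37 (SE 0.16). Osteoblast and bone matrix genes differed by 0.05 (camera adjusted p = 0.628), with Postn, periostin, at -0.52 (SE 0.17) and Enpp1 at 0.31 (SE 0.14), the latter with 1 of 2 probes on that side. With slide as a block that list's difference was 0.36 (adjusted p = 5.24e-11, range over alternatives 5.24e-11 to 0.815), and it was -0.02 without control 5 or without unloaded 2. The 20 osteoclast genes divided into 10 with a positive and 10 with a negative difference (mean -0.02, camera adjusted p = 0.284), Traf6 standing at -0.48 (SE 0.14) and Ocstamp at 0.37 (SE 0.13). Without unloaded 2 that list was called, at -0.09 (adjusted p = 0.0374, range over alternatives 0.0374 to 0.861). Fibrillar matrix and remodelling genes differed by -0.05 (camera adjusted p = 0.138), with Loxl2 at -0.65 (SE 0.31) and P4ha1 at -0.33 (SE 0.16). They were called in opposite directions under different choices, higher with slide as a block (0.40, adjusted p = 2.29e-14) and lower without control 5 (-0.14, adjusted p = 0.00129) or unloaded 2 (-0.14, adjusted p = 0.00628), while without control 2 the difference was 0.01, the range over alternatives being 2.29e-14 to 0.852. Control 5, the only control on slide 2, lay at -0.46 relative to the other controls for these genes. The unadjusted 95% intervals of Mepe, Fbln7, Postn, Enpp1, Traf6 and Ocstamp excluded 0, with adjusted p between 0.227 and 0.304. Within slide 2 the sign turned for Postn (0.08), Loxl2 (0.30) and P4ha1 (0.10).

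Markers of marrow and of attached tissue, apart from the T and NK cell list, were not called in the comparison of all arrays, but the calls of many of these lists depended on single arrays. Skeletal muscle genes differed by -0.12 with SDs of 0.48 and 0.41 (camera adjusted p = 0.0628), with 25 of 30 members negative. The difference was 0.01 without control 2 and -0.04 without control 3. The members with the smallest p were Tnnt1, a troponin of slow muscle fibres, at 0.27 (SE 0.11), and Mb, myoglobin, at -0.53 (SE 0.24). With slide as a block the list was called higher, at 0.32 (adjusted p = 0.00145), and it was called lower without control 1 (-0.28), control 5 (-0.19), unloaded 1 (-0.30) or unloaded 3 (-0.13), the adjusted p over alternatives ranging from 1.88e-05 to 0.685. Adipocyte genes differed by -0.11 (camera adjusted p = 0.104), with Car3 at -0.42 (SE 0.22, but 0.24 within slide 2) and Lpl at -0.32 (SE 0.20, but 0.31 within slide 2), and were called without control 1 (-0.20, adjusted p = 0.00722) or unloaded 5 (-0.18, adjusted p = 0.00323), with a range over alternatives of 0.00206 to 0.569. The adipocyte difference shrank to -0.04 without control 2 and to -0.05 without control 3. Erythroid genes differed by -0.08 (camera adjusted p = 0.0571), with Kel at -0.43 (SE 0.14) and Fech at 0.34 (SE 0.11), the latter with 1 of 2 probes on that side. They were called without control 1 (-0.10), control 2 (-0.10), control 4 (-0.09), unloaded 1 (-0.11) or unloaded 4 (-0.12), but differed by -0.02 without control 3 or without unloaded 5 (range of adjusted p over alternatives 0.00590 to 0.685).

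B cell genes differed by -0.09 (camera adjusted p = 0.0628), with Ebf1 at -0.35 (SE 0.12) and Fcer2a at 0.26 (SE 0.10). They were called without control 1 (-0.09), control 2 (-0.11), control 3 (-0.11), control 4 (-0.09), unloaded 2 (-0.14) or unloaded 3 (-0.10), and with slide as a block (-0.22, adjusted p = 4.26e-05), but differed by -0.04 without control 5 (adjusted p = 0.366, range over alternatives 4.26e-05 to 0.574) and by -0.05 without unloaded 5. Monocyte and macrophage genes differed by -0.08 (camera adjusted p = 0.0628), and were called without control 1 (-0.13), control 4 (-0.10) or unloaded 2 (-0.11), but differed by -0.02 without control 3 (range of adjusted p over alternatives 0.00745 to 0.433). In that list Cx3cr1, a chemokine receptor, was lower when adjusted over the list alone, at -0.97 (SE 0.26), while Ccr2 had -0.30 (SE 0.09); in both genes the other of 2 probes had the opposite sign. The neutrophil and precursor list had a mean difference of 0.00337 (camera adjusted p = 0.155), with Csf3r at -0.48 (SE 0.14) and Stfa2 at 0.42 (SE 0.15), and was called without control 4, at -0.06 (adjusted p = 0.0318, range over alternatives 0.0318 to 0.685). Endothelial genes differed by -0.06 (camera adjusted p = 0.115), with Sox18 at -0.46 (SE 0.14), and were called without control 1 (-0.09) or unloaded 2 (-0.11), with adjusted p over alternatives between 0.0229 and 0.685. Their difference was -0.03 without unloaded 5 and turned to 0.08 within slide 2, which has 1 control. Megakaryocyte and platelet genes differed by 0.02 (camera adjusted p = 0.661), with Mmrn1 at -0.34 (SE 0.14, but 0.23 within slide 2) and 1 of its 2 probes on that side, but were called lower with slide as a block (-0.18, adjusted p = 0.0185, range over alternatives 0.0107 to 0.969).

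Inflammatory mediator genes were not called by camera. Their mean differed by 0.08, or -0.01 with median scaling, which moves all lists alike, with SDs of 0.01 in control and 0.04 in unloaded animals, and all 5 unloaded animals lay above the controls (exact permutation p = 0.00794, or 0.123 adjusted over the lists). Fry gave an adjusted p of 0.0262, whereas camera, which compares the list with other genes, gave 0.303; the median difference of all genes was 0.05. Il6 was higher when adjusted over the list alone, at 0.41 (SE 0.10), with Ccl2 at 0.28 (SE 0.09), Osm at 0.30 (SE 0.10) and Tnfaip3 at -0.26 (SE 0.10). Circadian clock genes differed by 0.14 (camera adjusted p = 0.186; exact permutation p = 0.0397, or 0.246 adjusted over the lists). The test for change in either direction passed for them, with a fry mixed adjusted p of 0.0121. Per1 was the 1 member called when adjusted over the list alone, with Nr1d1 at 0.35 (SE 0.12) and 1 of its 3 probes on that side, Npas2 at 0.42 (SE 0.17) and Bhlhe41 at 0.25 (SE 0.11). Among immediate-early and load-responsive genes (mean 0.03, camera adjusted p = 0.467), 2 were called when adjusted over the list alone and went opposite ways. Ccn1, a matricellular gene induced by mechanical load, had 0.64 (SE 0.17), and Nr4a2, a nuclear receptor, -0.39 (SE 0.11). In the Wnt pathway list (mean 0.04, camera adjusted p = 0.761) the secreted Wnt modulator Sfrp2 was lower when adjusted over the list alone, at -0.58 (SE 0.14), and Kremen1 had 0.45 (SE 0.13) with 1 of 2 probes on that side. The list of TGF-beta, BMP and IGF pathways had a mean of -0.02 (camera adjusted p = 0.328), with Inhba at -0.43 (SE 0.16) and Igf1r at -0.35 (SE 0.13). With slide as a block, which rests on the 1 control of slide 2, camera called 4 of these lists higher: circadian clock (0.17, adjusted p = 0.0112), immediate-early (0.17, adjusted p = 0.00790), Wnt (0.20, adjusted p = 5.77e-05) and TGF-beta, BMP and IGF (0.14, adjusted p = 0.00589). Over the alternatives of each the highest adjusted p was 0.595, 0.856, 0.949 and 0.797, and those blocked values were the lowest.

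The remaining lists were not called in the comparison of all arrays, but 5 were with slide as a block, each lower and each resting on the 1 control of slide 2. Interferon response genes had a mean difference of -0.07 (camera adjusted p = 0.0723), with Stat2 at -0.25 (SE 0.11). They were called without control 1 (-0.14), control 2 (-0.10) or control 4 (-0.09) and with slide as a block (-0.18, adjusted p = 0.00145), but differed by 0.01 without control 3 (adjusted p = 0.689, range over alternatives 6.10e-05 to 0.689). Genes of ER stress and the amino acid response had -0.05 (camera adjusted p = 0.0628), and Hsp90b1, a chaperone of the endoplasmic reticulum, was lower when adjusted over the list alone, at -0.44 (SE 0.11); the list was called without control 1 (-0.07) or unloaded 2 (-0.08), with adjusted p over alternatives between 0.0229 and 0.758. Ribosomal protein genes had 0.07 (camera adjusted p = 0.303), and Rps19 was higher when adjusted over the list alone, at 0.53 (SE 0.13) with 2 of 3 probes on that side. That list was called higher without control 3 (0.11, adjusted p = 0.0428) or unloaded 1 (0.13, adjusted p = 0.0192) and lower with slide as a block (-0.13, adjusted p = 0.00270), the range over alternatives being 0.00156 to 0.792. The list of the proteasome and muscle atrophy ligases had -0.03 (camera adjusted p = 0.129), with the ligase Fbxo32 at 0.30 (SE 0.12), and was called without control 4 (-0.07) or unloaded 2 (-0.06) and with slide as a block (-0.12, adjusted p = 0.00591, range over alternatives 0.00545 to 0.973). Oxidative phosphorylation genes had -0.03 (camera adjusted p = 0.129), with Cox7b at -0.60 (SE 0.23), and were called without control 1 (-0.05), control 4 (-0.07) or unloaded 2 (-0.05) and with slide as a block (-0.12, adjusted p = 0.00145, range over alternatives 0.00101 to 0.761). Glycolysis and hypoxia genes had -0.03 (camera adjusted p = 0.134), with the glucose transporter Slc2a1 at 0.31 (SE 0.11), and were called without control 1 (-0.06) or control 4 (-0.05), with adjusted p over alternatives between 0.0387 and 0.685. Oxidative stress defence genes had -0.01 (camera adjusted p = 0.221), with Cybb at -0.40 (SE 0.11), and were called without control 4 (-0.06) and with slide as a block (-0.14, adjusted p = 0.00589, range over alternatives 0.00278 to 0.973). Genes of fatty acid oxidation and fasting had -0.00453 (camera adjusted p = 0.405), with Acaa2 at 0.31 (SE 0.13, but -0.16 within slide 2), and those of cholesterol and fatty acid synthesis 0.02 (camera adjusted p = 0.703), with Mvk at 0.28 (SE 0.10, but -0.02 within slide 2). For 7 uncalled lists the mean, the median and camera's direction differed in sign: neutrophil and precursor, megakaryocyte and platelet, TGF-beta, BMP and IGF, immediate-early, oxidative phosphorylation, oxidative stress defence, and cholesterol and fatty acid synthesis. Leaving out 1 array turned the sign of the mean in 13 uncalled lists, so no direction is read from lists near 0. Within slide 2 the mean difference had the sign of the whole comparison in 22 of 31 lists, and with slide as a block camera called 18 lists, 15 of them not called in the comparison of all arrays. Those calls used the preset correlation, and an estimated one was not run with the block or with an array left out. Of 138 genes that the naming rule takes, 27 had the opposite sign within slide 2 and 49 lay there outside their 95% interval of the whole comparison.

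No gene was called lower in the comparison as designed. Of its alternatives, eBayes with trend and robust options called Slfn4 lower (adjusted p = 0.0382, range over alternatives 0.0382 to 1.00). The 6 genes with the smallest p among those lower in unloaded bone had adjusted p between 0.143 and 0.181, and in each all 5 unloaded animals lay below the controls. Slfn4, a Schlafen family gene of myeloid cells, had the largest difference, from -0.37 ± 0.31 to -1.40 ± 0.29 (SD, n = 5 each), 2.05-fold lower, but it was 0.54 lower within slide 2 (log2 fold change -0.54 there against -1.03 overall). C5ar2, a receptor of complement C5a, had -0.92 (SE 0.17), Reln, the extracellular protein reelin, -0.73 (SE 0.13) and Prss35 -0.51 (SE 0.09). Cdkn1b, a cyclin-dependent kinase inhibitor, had -0.63 (SE 0.11), and 2 of its 3 probes shared that sign. The heat shock gene Hsph1 was the remaining one.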

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

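The tests of slide in this part were chosen after the result was seen. Within groups of 5 animals, 348 sets of values of lists, named genes and array measures were searched for an animal far from the other 4. Of the 348 sets 21 had one, a share close to the 5 percent that chance gives. In 10 of the 21 the animal was unloaded animal 5. Its negative control spots had an SD of 11.9 intensity units against 5.15 to 6.45 on the other unloaded arrays. It had the lowest log2 signal of Cd44 (2.56), Csf3r (0.34), Gfi1 (0.59), Pax5 (-2.20), Stab2 (-0.51), Selp (-1.02), Ddx58 (-2.65), Acadl (-0.95) and Cat (1.76). In Pax5, a B cell gene, the other unloaded animals lay between -0.11 and 0.54.

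The array of unloaded animal 5 stood apart over all probes too, at 65.4 on the first principal component, which held 36.5% of the variance, while the other arrays lay between -39.1 and 21.0. Noise of dim probes was argued against: over the 9638 brightest probes its mean correlation with its own group was still 0.960, against 0.975 to 0.986 for the other 9. Slide was argued against as well, since unloaded animal 4, on the same slide, scored 11.8, within the range of the others. The scale of the array was argued against, because after quantile normalization it still scored 64.2, with the others between -31.1 and 19.8. This array also had the lowest share of spots well above background, at 89.8%. The tests above do not exclude a fault of this single array. RNA quality and the animal itself stay open too, and no biological explanation was tested.

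The flagged values of the other animals are given as values and are not read as more than chance. Among lists, the osteoblast and bone matrix mean of unloaded animal 2 lay at 0.30 relative to the control mean, above -0.07 to 0.01 in the others. The B cell mean of control 5 was 0.20, against -0.09 to -0.01 in the other controls. The ribosomal protein mean of unloaded animal 1 was -0.15, against 0.08 to 0.15 in the others. Unloaded animal 2 had the lowest signal of its group for Ddit4 (4.32, the others between 4.80 and 4.86) and Klrb1c (-1.43). Unloaded animal 4 had the lowest Runx2 (0.68, the others between 1.09 and 1.11). Control 3 had the highest Kel (3.38) of its group and control 4 the lowest Rps19 (4.31). Control 5 had the lowest Plod1 (-0.26) and Lrp6 (-2.39) and the highest Nog (-2.19).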

How the results depend on the processing

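Slide as a random block, slide 2 on its own and the fit without both animals numbered 5 were chosen after seeing the data. The count of 1 called probe was the same under 18 of 30 alternatives. It was 3 with trend and robust eBayes (Ddit4 and Foxa2 higher, Slfn4 lower), 0 with a minimum fold of 1.2, 0 with body weight as a covariate, where Ddit4 had an unaltered log2 fold change of 1.17 and an adjusted p of 0.0511, and 3 with slide as a fixed block, Ddit4 not among them. It was 0 without both animals numbered 5, 0 on slide 2 alone, and 0 to 2 with 1 array left out, Foxa2 joining Ddit4 without control 2. Ddit4 was called in 19 of 28 alternatives, with log2 fold changes from 1.08 to 1.28. The 28 leave out the minimum fold of 1.2, under which Ddit4 was not called. They also leave out the test of 1 probe per gene, which called 1 gene.

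Against 5 lists called, 11 were called at an adjusted p below 0.10, 18 with slide as a fixed block, 18 on slide 2 alone, 8 without both animals numbered 5, 9 with the mean of all probes of a gene, 0 with an estimated correlation, 3 with fry, 0 by exact permutation after adjustment, and 6 to 14 with 1 array left out. The highest, 14, came without control 1 or without control 4. The 0 by exact permutation carries little weight. Heat shock genes had the smallest p that test can give, 0.00794, and it became 0.123 after adjustment over the lists. The T and NK cell list reversed with slide as a fixed block (-0.0096) and on slide 2 alone (-0.0091). The cartilage list was not called with slide as a random block (adjusted p = 0.0609; 7.41e-18 to 0.282 over its alternatives). For all of these the cause was not tested, except that slide 2 has 1 control. The glucocorticoid-responsive and proliferation lists were called by camera under all 28 alternatives that kept its preset correlation, and heat shock under 26, with slide as a fixed block and slide 2 alone as the exceptions. At that correlation camera also called a median of 10 lists on other splits of the arrays, so these counts do not set a list apart from chance. Proliferation was not called by fry (adjusted p = 0.435), and its difference was -0.05 without both animals numbered 5. Over 170 gene and list values, 4448 of 4759 alternative values counted as the same. A called value had to keep its sign and its call. An uncalled value had to stay uncalled and move by less than 1 SD, whatever its sign. Nearly all of the 170 values were not called, so the count says little about direction, and 177 values not called changed sign.

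The replicate number names different animals in the 2 groups. As a replicate block it left 1 called probe and gave 8 called lists; deviations of same-numbered animals correlated between -0.14 and 0.18, and 1 of 5 animals correlated best with its own number. All arrays were scanned on 1 day with 1 scanner, so no block of scan date was run. Signal over background limits the dim genes: 2545 probes were too dim or too often marked to be tested.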

Other observations

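The tests of slide and of unloaded animal 5 alone in this part were chosen after the result was seen. Outside the lists, several genes chosen after their values were seen separated all 5 unloaded from all 5 control animals without passing the adjustment in the comparison as designed. Cirbp, an RNA-binding protein induced by cooling, had a log2 fold change of 0.82 (SE 0.15, adjusted p = 0.181), and Depp1, a target of FoxO transcription factors, 0.72 (SE 0.13, adjusted p = 0.181). Foxa2, a forkhead transcription factor, had 0.91 (SE 0.14, adjusted p = 0.131), and was called with trend and robust eBayes and without control 2. The aldehyde dehydrogenase Aldh1a7 had -1.55 (SE 0.29, adjusted p = 0.181), and Nmrk2, a kinase of NAD synthesis found in muscle, -1.05 (SE 0.21, adjusted p = 0.186).

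Chance as the source of the single called probe was tested on 100 of the 126 splits of the 10 arrays into groups of 5, the real one included. As many probes were called in 4 of them, and the highest other count was 2, so over the splits drawn chance is excluded at the 5 percent level by a narrow margin. Over all splits this is not settled, since 3 more such splits among the 26 not drawn would reach that level, and the splits take no account of slide. Of the 2 splits with 2 calls, 1 put the 4 arrays of slide 1 with unloaded animal 2, so it followed slide as closely as the real split does; with slide as a block Ddit4 had a log2 fold change of 1.21 and an adjusted p of 0.267. Over its alternatives that adjusted p lay between 0.000660 and 0.414. At an unadjusted p below 0.05 that split gave 9225 probes and the real one 6225. For the 5 lists called by camera chance is not excluded, since 97 of the 100 splits called as many and the highest other count was 22. Camera at its preset correlation therefore called a median of 10 lists on the other splits, which points to genes of a list that vary together between animals.

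For the higher glucocorticoid-responsive genes in unloaded femur, slide as the whole cause is not excluded, although the list was still called by camera at its preset correlation with slide as a fixed block (0.21, adjusted p = 0.00145) and as a random block (0.21, adjusted p = 0.000605), the range over alternatives being 0.000170 to 0.0192. The fixed block rests on slide 2, where the list was 0.21 higher in the 3 unloaded animals than in control 5, the single control there, which lay at -0.03 relative to the other controls (SE of the difference 0.08, from the spread within both groups over all arrays). The random block removes little of slide, since arrays of a slide correlated at -0.03 in that fit, so the call it kept does not argue against slide. Unloaded animal 5 alone is argued against, since the difference without it was 0.19 (SE 0.04). A trend with signal level is argued against, since the list's mean lay at percentile 100 of 10000 random lists matched on mean signal. Whether unloading of the bone or another effect of suspension and handling on the animal underlies it was not tested, because every unloaded animal was suspended, and no hormone level was analysed here.

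For the lower heat shock genes the values on slide 2 go with slide. On slide 2 the difference was -0.071 (SE 0.07), the call was lost with slide as a fixed block (adjusted p = 0.146, range over alternatives 4.49e-05 to 0.163), and control 5 lay at -0.09 relative to the other controls (SE 0.07), as slide would need. This rests on 1 control, so slide may account for the pattern but is not settled as its cause. With slide as a random block camera still called the list (-0.17, adjusted p = 4.49e-05). Arrays of a slide correlated at -0.03 in that fit, so that block removes little of slide and does not decide the question. Unloaded animal 5 alone is argued against by a difference of -0.14 (SE 0.03) without it, and a trend with signal level by percentile 0 among 10000 matched random lists.

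A lower temperature of the limb or body of suspended animals is a candidate explanation that links lower heat shock genes with higher Cirbp. It was tested on Rbm3, another cold-induced RNA-binding protein, whose value had not been seen when the test was set. Rbm3 had a log2 fold change of 0.44 (95% interval 0.12 to 0.75, adjusted p = 0.252), and 4 of 5 unloaded animals lay above all controls, as the hypothesis needs. Of all 38629 probes 3939 were higher at an unadjusted limma p below 0.05, so 1 gene that passes is weak evidence. Within slide 2 the differences were smaller, at 0.08 for Rbm3 and 0.37 for Cirbp, and control 5 lay 0.26 and 0.45 above the other controls, so slide or that animal may account for part of them. No temperature was analysed here.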
